A study of Mus musculus with 2 samples.

How the data were processed

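Single-cell RNA was measured in 2 libraries, 1 per group. Both held cells isolated from breast tumours of inAd-Chaser-mTmG mice and sorted as positive for EGFP and negative for tdTomato, per the labels' protocols. The Met-1 transplant and the PyMT tumour are the tissues that the sample labels give. The series design text names EO771 as the implanted line, which differs from the sample label; the sample label is followed here. The unit of the deposited matrices is a whole-number UMI count per gene and barcode, made with Cell Ranger 3.1.0 against build mm10, per the submitters' processing notes and, for the software version, per the file headers. The annotation release is not given in the sources used here, and neither is whether the barcodes had been filtered for cells. Both libraries listed the same 31054 gene rows, of which 71 share a symbol with another row and 1 is EGFP. The table held 0 rows named for tdTomato, Cre, rtTA or the PyMT transgene. No other genome or annotation was used, so no coordinates are given.

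Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% of UMIs in the 13 mitochondrial genes. Doublets were called with Scrublet within each library at its automatic threshold, with an expected rate of 0.8% per 1000 barcodes (1.96% and 0.495%) and a cap of 2 times that rate. Of the Met-1 transplant barcodes, 316 exceeded the mitochondrial limit, 21 had too few genes and 16 were doublet calls. Some barcodes met more than 1 of these, so 332 were left out and 2119 of 2451 were kept. In the PyMT tumour, these numbers were 27, 15 and 1, with 30 left out and 589 of 619 barcodes kept. Kept cells of both libraries were scaled to 10000 counts, log-transformed and clustered together without integration. Clustering used 2000 variable genes among those in at least 3 cells, values clipped at 10, 30 principal components, 15 exact nearest neighbours and the Leiden algorithm at resolution 0.5. Fibroblast-like cells were clustered again at resolution 0.4.

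A cluster was called like a cell type from 16 fixed marker lists, when at least 3 markers were present in 25% of its cells and stood 2-fold above the rest. Where several types passed, the type with the largest share of its markers passing gave the name. A cluster in which another type also had 50% or more of its markers in at least 50% of cells was called mixed and entered no class comparison. The leading genes of a cluster are the 5 highest by fold among genes in at least 25% of its cells.

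With 1 library per group there was no statistical test. Counts were summed over the cells of a class and library, and expressed as CPM, the share of all UMIs scaled per 1e6, with exact Poisson 95% intervals. Ratios between libraries have exact conditional binomial intervals, and shares of cells have exact Clopper-Pearson intervals. These intervals cover counting error only, not the spread between mice or tumours. Genes entered a comparison with at least 50 summed UMIs in at least 1 library, and were counted as higher or lower when the ratio of (CPM + 10) was at least 2-fold. Where a library had 0 UMIs of a gene, the fold is a lower bound against a floor of 3 counts over the class. The lower limit of the exact 95% interval is smaller than this bound. Classes other than fibroblast-like cells were compared with at least 30 cells per library; the 11 fibroblast-like cells of the PyMT tumour are below that number and were compared as the design had set. Values within a library needed at least 20 cells, except for fibroblast-like cells and their subclusters, where values of the 11 PyMT cells are given.

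The genes named in the text follow a fixed rule. It takes the 12 highest and 12 lowest genes by log2 ratio in fibroblast-like cells, the 6 highest and 6 lowest in all kept cells, and the 4 highest and 4 lowest in each other class. Mitochondrial, ribosomal protein, haemoglobin, Gm-numbered, Rik, pseudogene and antisense rows were left out of these. It adds the 2 highest and 2 lowest measured members of each gene list, and the 6 adipocyte identity genes with the most UMIs. A gene that this rule selects is not reported here. A list member was measured with at least 20 UMIs in either library. The median log2 ratio of each of 24 gene lists was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. After the results were seen, genes apart were also counted with the median log2 ratio over the other classes taken from each gene that had a ratio in at least 3 of them. The marker lists, the gene lists, the rules and all alternatives not marked as added were set before the data were examined.

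Shares of cells with a UMI were compared after thinning every cell to 1000 UMIs, and the value without thinning is given beside it. A cell was counted as cycling with at least 2 UMIs over the genes of the G2 and M phases. The ratio step was tested on simulated counts with 4-fold differences planted in 200 genes. Summed counts per library were drawn with Poisson error around the mean profile of both libraries, without spread between cells. Planted genes were taken from those with enough expected UMIs in the smaller library. The rates that follow therefore cover counting error only, and not single cells that carry much of a gene's RNA. In the simulation of fibroblast-like cells, run on 7518 genes, 190 of 200 planted genes were recovered and 584 of 7318 unchanged genes (7.98%) passed the size rule. In that of all kept cells, run on 12059 genes, 122 of the 168 planted genes that could be tested were recovered and 0 of 11891 unchanged genes passed. Alternatives covered the cell filters, doublet calls, clustering settings, scaling, the added CPM, the count minimum, equal numbers of cells, the thinning depth and the size rule. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, pandas 2.3.3 and matplotlib 3.10.9.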

Results

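RNA of single cells was counted in breast tumours from mice in which a doxycycline pulse marks adipocytes and their descendants with EGFP. EGFP-positive, tdTomato-negative cells of a Met-1 transplant (1 library, 2451 barcodes) and of a PyMT tumour (1 library, 619 barcodes) were compared. After filtering, 2119 Met-1 cells (86.5%) and 589 PyMT cells (95.2%) were kept, with a median of 7706 and 3470 UMIs and of 2401 and 1208 genes per cell. The Met-1 library held 19908483 UMIs in kept cells and the PyMT library 4295404. With 1 mouse-derived library per group, no difference between the tumours has a replicate check, and intervals in parentheses are 95% intervals for counting error only.

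The sorted cells of both tumours were mostly immune cells, which made up 80.7% (78.9 to 82.3) of Met-1 cells and 81.3% (77.9 to 84.4) of PyMT cells. Macrophage or monocyte-like cells were the largest class in both, with 811 cells (38.3%, 36.2 to 40.4) in Met-1 and 203 cells (34.5%, 30.6 to 38.5) in PyMT. Fibroblast-like cells were more frequent in the Met-1 transplant (224 cells, 10.6%, 9.29 to 12) than in the PyMT tumour (11 cells, 1.87%, 0.936 to 3.32). Mural-like cells, led by the pericyte genes Rgs5, Higd1b, Abcc9 and Kcnj8, were seen only in Met-1 (145 cells, 6.84%, 5.81 to 8, 0 of 589 PyMT cells, up to 0.624%). NK-like cells made up 8.68% (7.52 to 9.96) of Met-1 and 0.509% (0.105 to 1.48) of PyMT cells. T-like cells made up 15.6% (14.1 to 17.2) and 8.15% (6.07 to 10.7), and B-like cells 12.3% (10.9 to 13.7) and 5.26% (3.60 to 7.39).

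The PyMT tumour had higher shares of neutrophil-like and luminal-like cells. Neutrophil-like cells, led by S100a9 and S100a8, made up 32.4% (28.7 to 36.4, 191 cells) of PyMT and 1.75% (1.23 to 2.40, 37 cells) of Met-1 cells. Luminal epithelial or tumour-like cells, led by the milk gene Csn3 and the keratins Krt8 and Krt18, made up 16.8% (13.9 to 20.1, 99 cells) and 1.94% (1.39 to 2.62, 41 cells). In 4 of the other filter and clustering settings the fibroblast-like cluster led by Cilp and Thbs4 was joined to the mural-like cells, and the Met-1 fibroblast-like share was then 3.93% to 4.06%. The shares are of sorted cells, and the sort and the depth gap of 7706 to 3470 median UMIs stand beside every share.

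**Figure D1:**
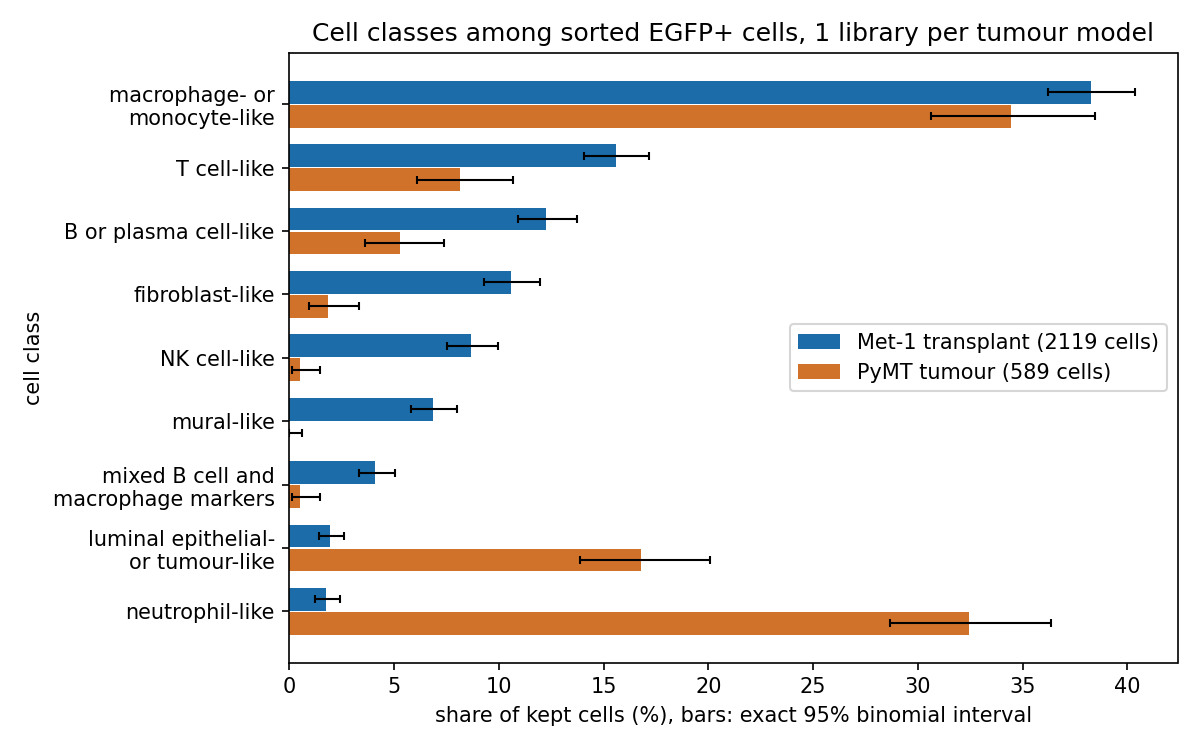
Share of kept cells in each class in the Met-1 transplant (2119 cells) and the PyMT tumour (589 cells). Bars show Clopper-Pearson 95% intervals, which cover counting error only.

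EGFP RNA was present in nearly all classes and was highest in neutrophil-like cells, at 13100 CPM (12414 to 13815) in Met-1 and 8809 CPM in PyMT. In the Met-1 transplant, macrophage-like cells had 4344 CPM (4294 to 4395), mural-like cells 4244 (4145 to 4344), B-like cells 3155 (3045 to 3267), T-like cells 2551 (2494 to 2610) and fibroblast-like cells 2479 (2431 to 2529). An EGFP UMI was present in 97.2% of Met-1 macrophage-like, 97.6% of T-like and 96.0% of fibroblast-like cells, and in 58.5% of luminal-like cells, which held the least EGFP (207 CPM, 176 to 241). At 1000 UMIs per cell these shares were 90.5%, 82.2%, 69.1% and 12.9%, with 36, 4, 4 and 10 cells left out, and the median depth without thinning was 7363, 7962, 17931 and 5302 UMIs. In the PyMT tumour, luminal-like cells had 1876 CPM of EGFP (66 of 99 cells with a UMI, 45.3% at 1000 UMIs), fibroblast-like cells 649 CPM (515 to 808, 8 of 11 cells, 36.4% at 1000 UMIs) and B-like cells 155 CPM (77.5 to 278, 5 of 31 cells, 9.68% at 1000 UMIs). EGFP was 9.08-fold (7.75 to 10.7) lower in luminal-like cells of Met-1 than of PyMT, and 20.3-fold (11.4 to 40.8) higher in B-like cells. In luminal-like cells, 1 cell held 78 of the 159 Met-1 EGFP UMIs, and the median per cell was 69.0 CPM in Met-1 and 244.5 CPM in PyMT. The Met-1 tumour came from an implanted line, and whether its luminal-like cells carry the label construct was not tested.

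**Figure D2:**
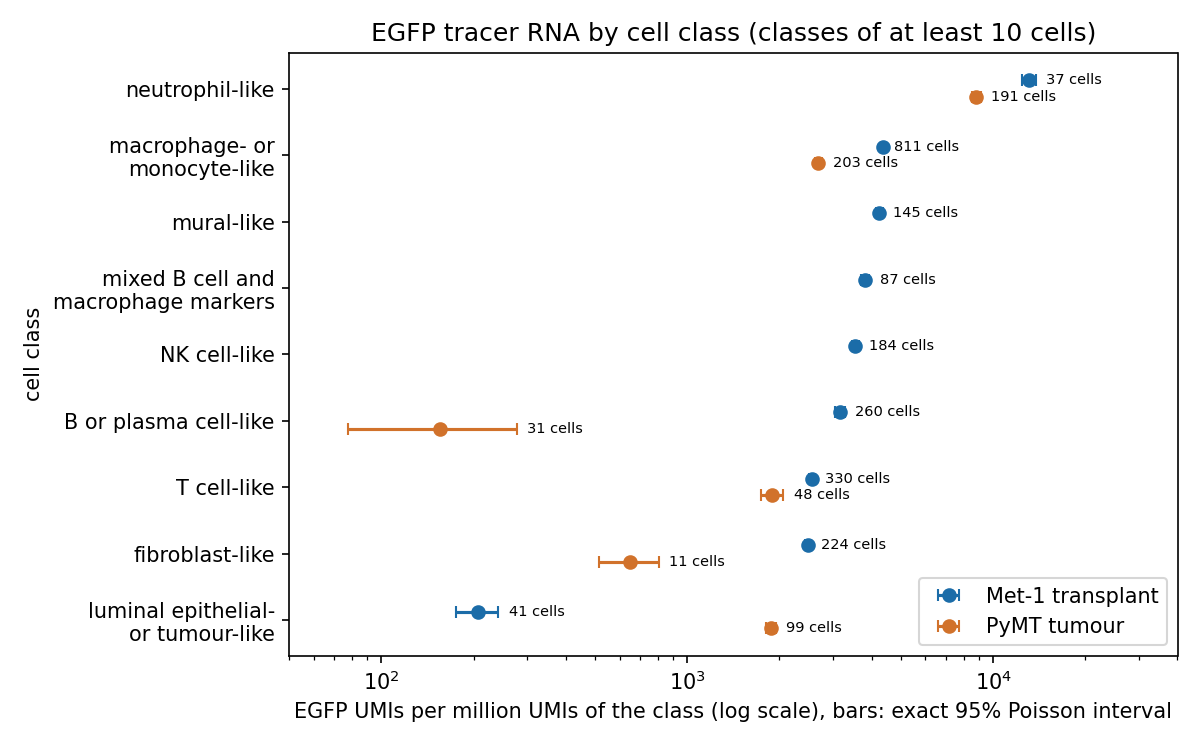
EGFP CPM by class and library, with Poisson 95% intervals for counting error. Met-1 luminal-like cells had 207 CPM and Met-1 neutrophil-like cells 13100 CPM.

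Genes specific to mature adipocytes were nearly absent. The sort was made from the tumour fibroblast isolation, which sets which cells could be present. The near absence is therefore not shown to be a loss of adipocyte RNA by labelled cells. Adipoq, which encodes adiponectin, had 5 UMIs, all in 1 of 2708 cells. Over Adipoq, Plin1, Cidec, Lep and Adrb3 together, Met-1 fibroblast-like cells had 2 of 3987615 UMIs and PyMT fibroblast-like cells 0 of 123188, where 3 counts would be 24.4 CPM. Over all 13 adipocyte markers, fibroblast-like cells had 26.3 CPM (21.5 to 31.9) in Met-1 and 32.5 CPM (8.85 to 83.1) in PyMT, below the 43.0 and 105 CPM of T-like cells. At a depth of 1000 UMIs, 1.36% of Met-1 and 0% of PyMT fibroblast-like cells held a marker UMI, against 32.6% and 36.4% without thinning. Only 5 cells of both libraries held 10 or more UMIs over the 13 markers.

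Lpl, which encodes lipoprotein lipase, was the adipocyte identity gene with the most RNA in fibroblast-like cells, at 802 CPM (774 to 830) in Met-1 and 138 CPM (80.4 to 221) in PyMT, a ratio of 5.81 (3.62 to 9.99). In the cluster led by Clec3b alone, the Lpl ratio was 2.69 (1.66 to 4.65). At 1000 UMIs, Lpl was detected in 45.9% (39.2 to 52.7) of 220 Met-1 fibroblast-like cells and in 18.2% (2.28 to 51.8) of 11 PyMT cells (85.3% and 81.8% without thinning), with 4 Met-1 cells left out for depth. T-like cells, a type that should lack Lpl, had it in 0.614% of Met-1 cells at that depth (3.03% without thinning); median depths were 17931 UMIs in Met-1 fibroblast-like and 7962 in T-like cells. Mural-like cells had 584 CPM of Lpl (547 to 622), and macrophage-like cells 190 CPM in Met-1 and 131 in PyMT. Of the other 5 identity genes with the most UMIs, fibroblast-like cells had 22.6 and 8.12 CPM of Cebpa (1 UMI in PyMT), 15.8 CPM of Dgat1 in Met-1, 12 and 24.4 CPM of Pnpla2 (3 UMIs in PyMT), 9.78 and 0 CPM of Acsl1, and 21.6 and 24.4 CPM of Agpat2. Other classes held more of these, with Cebpa at 453 CPM in Met-1 macrophage-like cells and Dgat1 at 159 CPM in NK-like cells.

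**Figure D3:**
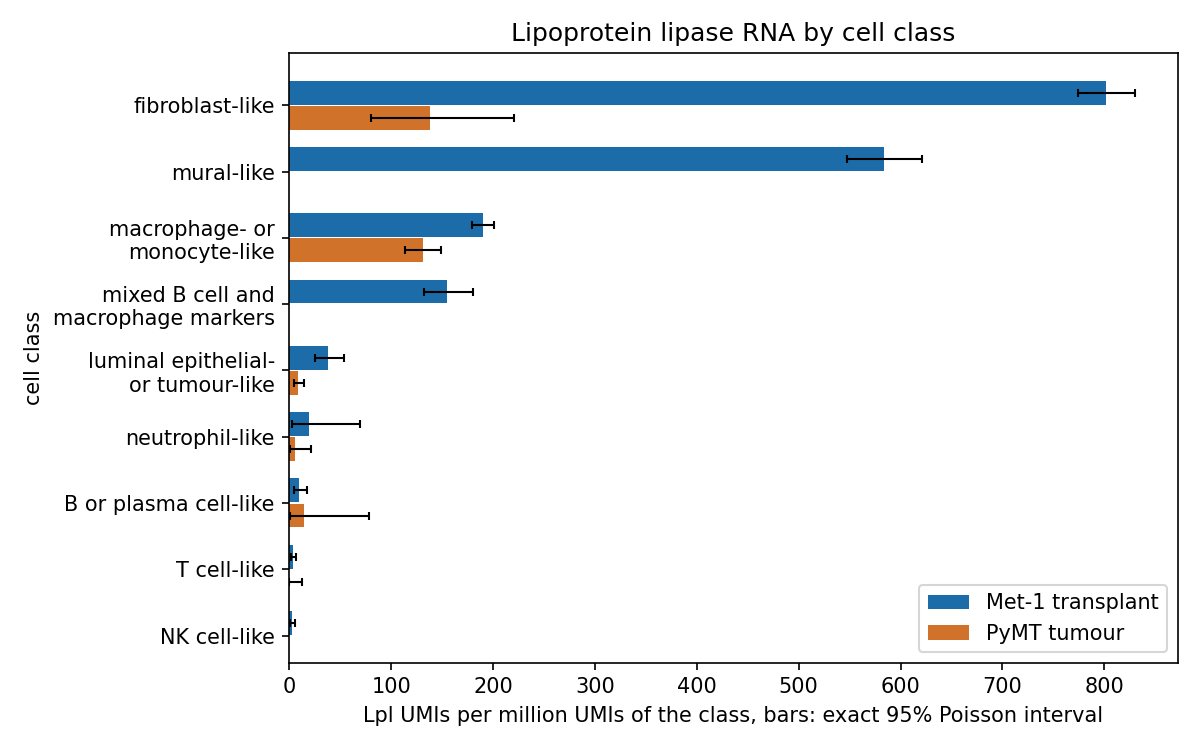
Lpl CPM by class and library, with Poisson 95% intervals for counting error. Met-1 fibroblast-like cells had 802 CPM and PyMT fibroblast-like cells 138 CPM.

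Fibroblast-like cells of the Met-1 transplant (224 cells, 138 in the cluster led by Cilp and Thbs4 and 86 in that led by Clec3b) were higher in genes such as Acta2, Tagln and Spp1 than the 11 of the PyMT tumour, all in the Clec3b cluster. Spp1 (osteopontin, ENSMUSG00000029304) was 75.1-fold higher (36.5 to 187, 7 PyMT UMIs, all in 1 cell), the smooth muscle actin gene Acta2 (ENSMUSG00000035783) 59.4-fold (16.4 to 491, 2 PyMT UMIs), and the collagenase Mmp13 48.0-fold (8.59 to 1895, 1 PyMT UMI). The protease inhibitor Serpine2 was 25-fold (13.6 to 52.1) and the actin-binding Tagln (ENSMUSG00000032085) 20.4-fold (10.8 to 44.7) higher. With 0 UMIs in PyMT, the growth factor Ptn was at least 20.7-fold higher, the collagen-binding integrin Itga1 12.5-fold, and the complement inhibitor Cd59a 11.4-fold. The insulin-like growth factor-binding proteins Igfbp3 and Igfbp2 were at least 10.2-fold and 8.67-fold higher, Ramp1 9.33-fold and Mest 7.01-fold. Spp1, Acta2, Tagln, Mmp13 and Serpine2 also lead a fibroblast-like subcluster made almost only of Met-1 cells, so the gene and the subcluster results are not independent.

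Genes higher in the PyMT fibroblast-like cells included Rcan1, Nr4a1, Mt2 and Cxcl1. The calcineurin inhibitor Rcan1 (ENSMUSG00000022951) was 14.8-fold (9.52 to 22.7), the nuclear receptor Nr4a1 11.1-fold (7.82 to 15.5), the hexokinase Hk2 10.8-fold (7.09 to 16.1), the metallothionein Mt2 (ENSMUSG00000031762) 10.4-fold (8.70 to 12.5), the neutrophil-attracting chemokine Cxcl1 7.24-fold (5.80 to 8.97) and the BMP antagonist Nbl1 7.07-fold higher in PyMT. Efhd1 was 8.92-fold, the cyclooxygenase Ptgs1 8.27-fold, Tmem100 7.76-fold and Tppp3 6.82-fold higher. Single cells carried much of the RNA of Fgl2 (9.83-fold, 32 of 48 PyMT UMIs), Htra3 (8.19-fold, 155 of 261), Rcan1 (17 of 33) and Mt2 (73 of 165). Without the top cell of each library the log2 ratio was -1.64 for Fgl2 (-3.01 with it), -1.82 for Htra3 (-2.99), -2.41 for Rcan1 (-3.31) and -2.55 for Mt2 (-3.29). Of 7850 genes, 1645 were at least 2-fold higher and 385 lower in Met-1, so 81.0% of the genes apart were higher, and 94.7% after centring on the median of the genes with 50 UMIs in both libraries (log2 -0.41). A minimum of 50 UMIs is 12.5 CPM in Met-1 but 406 CPM in PyMT; with 50 UMIs in both libraries, 11 genes were higher and 94 lower. After each gene was set against its median over the other classes, 719 of 5811 genes were higher and 250 lower (1045 and 227 before). Only 572 higher and 108 lower genes were in both counts.

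By fixed gene lists, the myofibroblastic list was higher in Met-1 fibroblast-like cells (15 of 20 measured genes higher, 1 lower, median log2 ratio 1.81, percentile 100 of random lists). Acta2 and Tagln were highest, while Postn (PyMT over Met-1 1.04, 0.933 to 1.17) was level and Cthrc1 was 2.5-fold (1.93 to 3.20) higher in PyMT. Collagens and matrix genes (13 higher and 1 lower of 42, median 0.39, percentile 100), with Tnc 12.1-fold higher (4.71 to 44.4) and Mfap5 2.42-fold lower (2.23 to 2.62), and matrix remodelling genes (6 higher of 23, median 0.59, percentile 99.9), with Plau at least 3.28-fold higher, also had higher medians than random lists. The inflammatory fibroblast list was lower in Met-1 (3 higher and 14 lower of 22, median -1.19, percentile 0), with Cxcl1 and Cxcl2 (9.25-fold, 4.72 to 17.0) lower and Il1r1 4.02-fold (1.56 to 14.8) higher. The adipose progenitor list had a lower median too (1 higher and 9 lower of 19, median -0.97, percentile 0), with Pi16 5.35-fold (4.80 to 5.96) and Wnt2 5.76-fold (3.88 to 8.33) lower and the growth factor receptor Pdgfrb 4.82-fold (2.53 to 10.6) higher. Lipogenesis genes had a lower median than most random lists (0 higher and 3 lower of 10, median -0.60, percentile 0.30), with Acly 3.96-fold (2.24 to 6.57) and Scd1 2.70-fold (1.13 to 5.53) lower.

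The immediate early list, which also holds heat shock genes, stands for cell dissociation. Immediate early genes had a low median in Met-1 fibroblast-like cells (1 higher and 6 lower of 20, median log2 ratio -0.63, percentile 0.34), although Jun was 3.76-fold (2.78 to 5.23) higher. Chemokines and cytokines had a low median as well (3 higher and 5 lower of 15, median -0.55, percentile 0.41), and interferon response genes a high median (7 higher and 3 lower of 25, median 0.58, percentile 98.8), with Cxcl9 26.7-fold higher (4.77 to 1054, 1 PyMT UMI) and Oas1a 4.26-fold lower. Tumour macrophage genes (5 higher of 15, median 0.58, percentile 99.1), milk genes (1 higher and 1 lower of 3, median 0.99, percentile 96.7), MHC class I genes (1 higher of 11, median 0.43, percentile 93.3) and mesenchymal transition genes (5 higher and 2 lower of 13, median 0.34, percentile 91.4), with Cdh11 6.28-fold higher, lay above the 90th percentile. Spp1 is a member of both the tumour macrophage and the milk list. The milk gene Csn3 stood at 1.76 CPM in Met-1 and 56.8 CPM in PyMT fibroblast-like cells. The milk list median therefore does not show more milk RNA in Met-1. Leaving out the top cell of each gene takes more from 11 PyMT cells than from 224 Met-1 cells, so ratios tend to rise by construction. Interferon genes rose from 0.58 to 1.15, and Wnt and Notch genes from 0.06 to 1.03. Antigen-presenting fibroblast genes (0.72 to 0.64) and G2 and M phase genes (0.75 to 0.69) fell. The medians without top cells therefore do not show that single cells set the low list medians. Without the top cell of each gene, the medians were 0.07 for immediate early genes (3 higher and 3 lower), -0.04 for chemokines (5 higher and 3 lower), -0.06 for lipogenesis genes (2 higher and 1 lower), -0.17 for the adipose progenitor list (4 higher and 5 lower), -0.78 for the inflammatory list (5 higher and 8 lower) and 1.12 for collagens.

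The other lists of fibroblast-like cells lay between percentiles 11.7 and 89.6. They were adipocyte identity (2 higher of 8, median log2 ratio 0.88, percentile 89.6), the lysosome (1 higher and 2 lower of 20, median 0.26, percentile 87.9), antigen-presenting fibroblast genes (0 of 7 apart, median 0.72, percentile 87.3), fatty acid oxidation (1 higher of 9, median 0.33, percentile 73.8) and the G2 and M phases (4 higher of 11, median 0.75, percentile 71.2). Hormone receptor genes (0 of 3 apart, median 0.40, percentile 37.5), YAP and TAZ targets (5 higher and 3 lower of 13, median -0.00, percentile 37.3), Wnt and Notch genes (5 higher and 3 lower of 17, median 0.06, percentile 34.2), hypoxia genes (3 higher and 2 lower of 20, median -0.03, percentile 23.4), the S phase (1 higher of 9, median 0.11, percentile 20.5) and TGF-beta genes (5 higher and 2 lower of 21, median -0.18, percentile 11.7) completed the lists. Within these, Ctgf was 8.35-fold (4.88 to 15.7), Wisp1 9.40-fold (3.21 to 45.7, 3 PyMT UMIs) and Inhba at least 4.25-fold higher in Met-1, and Axl 2.86-fold, Sfrp2 2.96-fold and Ltbp1 3.07-fold lower.

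**Figure D4:**
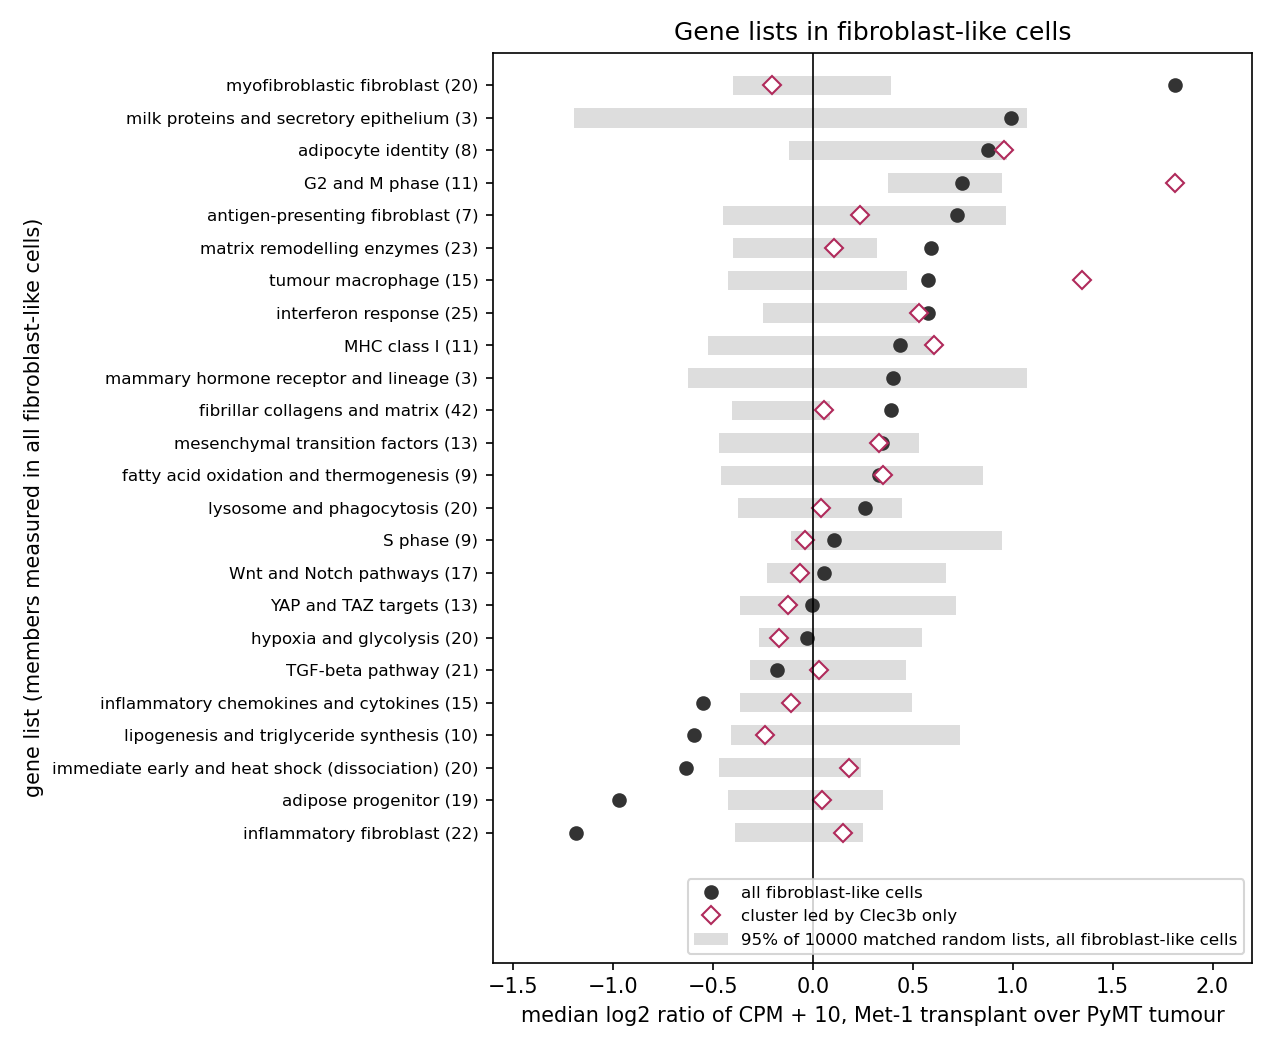
Median log2 ratio (Met-1 over PyMT) of each fixed gene list in fibroblast-like cells (224 and 11 cells). Grey bars show the range that held most medians of 10000 random lists. Open diamonds show the medians in the cluster led by Clec3b alone (86 and 11 cells). Over all fibroblast-like cells, the myofibroblastic list had a median of 1.81 and the inflammatory list of -1.19.

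Within the cluster led by Clec3b, the sole cluster that held fibroblast-like cells of both tumours (86 Met-1 and 11 PyMT cells), the differences in the myofibroblastic, inflammatory and adipose progenitor lists were not seen. Its cells were still unlike in kind, as 39 Met-1 and 0 PyMT cells lay in the subcluster led by Gdf10, and 40 Met-1 and 10 PyMT cells in that led by Pi16. This comparison was chosen after the results were seen. Members of the lists also mark the clusters. Clec3b, C3 and Ly6c1 of the inflammatory list and Pi16 of the adipose progenitor list lead the kept cluster. Col12a1 and Tnc of the myofibroblastic list are leading genes of the cluster left out. The list differences therefore shrink in part by construction, and their absence here does not show that like cells were alike in both tumours. Of 3503 genes, 538 were higher and 177 lower in Met-1, but 11 and 50 of the 388 genes with 50 UMIs in both libraries (41.9 and 406 CPM). The myofibroblastic list had a median log2 ratio of -0.21 (2 higher and 3 lower of 14, percentile 9.37), the inflammatory list 0.15 (3 higher and 5 lower of 19, percentile 90.9), the adipose progenitor list 0.047 (3 higher and 1 lower of 18, percentile 81.8) and collagens 0.06 (1 higher and 7 lower of 39, percentile 95.6). Immediate early genes had a median of 0.18 (4 higher and 4 lower of 20, percentile 98.2) and matrix remodelling genes of 0.11 (5 higher and 3 lower of 21, percentile 87.6). The matrix gene Postn was 4.28-fold (3.75 to 4.88) higher in PyMT and complement C3 5.06-fold (3.94 to 6.62) higher in Met-1. Cxcl1 was 3.89-fold, Nr4a1 5.22-fold and Hk2 5.31-fold lower in Met-1. In the Pi16 subcluster, Cxcl1 stood at 75.9 CPM (55.6 to 101) in Met-1 and 864 CPM (705 to 1048) in PyMT. Tumour macrophage genes (7 higher of 12, median 1.35 and 0.58 without top cells, percentile 100), interferon genes (6 higher and 1 lower of 21, median 0.53, percentile 99.4) and MHC class I genes (2 higher of 11, median 0.61, percentile 97.7) had higher medians in Met-1.

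Fibroblast-like cells formed 3 subclusters. The subcluster led by Spp1, Tagln, Acta2, Mmp13 and Serpine2 held 145 of 224 Met-1 fibroblast-like cells (64.7%, 58.1 to 71.0) and 1 of 11 PyMT cells (9.09%, 0.230 to 41.3). It took in all 138 cells of the cluster led by Cilp and Thbs4. The subcluster led by the adipose progenitor genes Pi16 and Dpp4 together with Sbsn, Sema3c and Akr1c18 held 40 Met-1 cells (17.9%, 13.1 to 23.5) and 10 of 11 PyMT cells (90.9%, 58.7 to 99.8). The subcluster led by Gdf10, Inmt, Vtn, Steap4 and Prg4 held 39 Met-1 cells (17.4%, 12.7 to 23) and 0 of 11 PyMT cells (up to 28.5%). At a resolution of 0.8 there were 5 subclusters, and the subcluster with the most Acta2 held 18.8% of Met-1 and 0% of PyMT cells.

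Over all kept cells, which differ in composition as given above, 845 of 11993 genes were higher and 433 lower in Met-1 (454 and 336 with 50 UMIs in both libraries). The granzyme Gzmc was 120-fold (77.4 to 196), Tagln 92.3-fold (59.7 to 151), Col8a1 36.7-fold, Mgp 32.8-fold and Col6a3 26.7-fold higher in Met-1, and the pericyte gene Rgs5 at least 467-fold (6501 and 0 UMIs). The luminal genes Wfdc2 (78.1-fold, 60.8 to 102), Csn3 (15-fold), Cd24a (14.5-fold) and Krt8 (11.6-fold), the glycolytic Aldoc (19.3-fold) and the neutrophil gene S100a8 (10.3-fold) were lower in Met-1. Collagens (39 higher and 0 lower of 42, median log2 ratio 2.56), the myofibroblastic list (14 higher of 20, median 2.26), matrix remodelling (16 higher and 1 lower of 25, median 1.44) and mesenchymal transition genes (10 higher and 1 lower of 15, median 1.42) were higher, with Pdgfrb 89.8-fold (47.3 to 197) and Cdh11 17.6-fold higher. Milk genes (1 higher and 6 lower of 10, median -1.81) were lower. List medians were below 0, with most members under 2-fold, for hypoxia genes (2 higher and 7 lower of 22, median -0.83), chemokines (1 higher and 8 lower of 24, median -0.78) and lipogenesis genes (0 higher and 5 lower of 14, median -0.75). The chemokine Cxcl3 was 106-fold (50.3 to 268) and Scd1 4.55-fold lower. Lpl was 4.78-fold (4.21 to 5.44) and Fabp4 14.7-fold (7.39 to 34.2) higher in Met-1.

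Macrophage-like cells (811 in Met-1, 203 in PyMT) were higher in Met-1 for the angiogenic factor Vegfa (11.2-fold, 7.50 to 17.6), the mitochondrial tRNA synthetase Lars2 (12.8-fold, 7.86 to 22.6) and the matrix gene Mgp (36.7-fold, 15.7 to 113). Cfd was at least 31.6-fold higher, with 367 of its 373 UMIs in 2 cells. The immediate early list, set for cell dissociation, had a median log2 ratio of 0.57 (6 higher and 14 under 2-fold of 20, percentile 99.98), with Hspa1b 7.54-fold and Jun 3.80-fold higher. Its median was also above 0 in luminal-like (0.65) and B-like cells (0.44), but below 0 in fibroblast-like (-0.63), T-like (-0.13) and neutrophil-like cells (-0.22). Jun was at least 2-fold higher in 5 classes. The median mitochondrial share of kept cells was 2.49% in Met-1 and 1.44% in PyMT. Collagens had a median of 0.71 (12 higher and 20 under 2-fold of 32, percentile 100), with Col1a1 19.4-fold higher and 162 of its 382 Met-1 UMIs in 1 cell. Chemokines had a median of -0.55 (7 lower and 15 under 2-fold of 22, percentile 0), with Cxcl1 3.93-fold and Ccl7 3.81-fold lower. Csn3 (19.4-fold), Lcn2 (16.1-fold), Vmn1r13 (10.4-fold) and Chil3 (6.52-fold, 230 of 268 PyMT UMIs in 1 cell) were lower. Of 8267 genes, 433 were higher and 94 lower (175 and 79 with 50 UMIs in both). After the median over the other classes was taken from each gene, 96 of 6343 were higher and 66 lower (346 and 70 before), with 35 and 6 genes in both counts. Csn3 was also found in PyMT T-like cells at 112 CPM. Col1a1 was found in Met-1 B-like cells at 55.3 CPM against 57.6 CPM in macrophage-like cells. Neither the milk nor the collagen RNA is therefore a mark of macrophage-like cells.

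Neutrophil-like cells (37 and 191) were lower in Met-1 for hypoxia genes (0 higher and 14 lower of 16, median log2 ratio -1.46, percentile 0), among them the prolyl hydroxylase Egln3 (at least 7.55-fold lower) and Bnip3 (6.41-fold, 3.31 to 14.2). Chemokines and cytokines were lower (1 higher and 8 lower of 15, median -1.07), with Cxcl3 15.6-fold and Mif 5.47-fold lower. Saa3 was at least 34.8-fold lower (135 of 346 PyMT UMIs in 1 cell), Chil3 51.0-fold (9.03 to 2027, 1 Met-1 UMI) and the heat shock gene Hspa1a 48.9-fold (8.65 to 1943, 1 Met-1 UMI). The interferon gene Ifi27l2a (6.08-fold, 4.83 to 7.69), Jdp2 (5.38-fold), the ectonucleotidase Entpd1 (5.10-fold) and Kpna4 (4.65-fold) were higher. Of 996 genes, 56 were higher and 189 lower in Met-1, but 34 and 18 with 50 UMIs in both libraries, where 50 UMIs are 481 CPM in Met-1 and 145 in PyMT. The numbers were 31 and 104 of 915 after the same step (50 and 164 before), with 13 and 88 genes in both counts.

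Luminal-like cells (41 and 99) were lower in Met-1 for Cxcl2 (192-fold, 53.0 to 1587, 2 Met-1 UMIs), the IGF-binding Igfbp2 (29.7-fold, 16.5 to 59.8) and the MHC class II chain Cd74 (14.9-fold, 11.4 to 19.9). Those of Met-1 may be cells of the implanted line, which was not tested. Antigen presentation genes (0 higher and 6 lower of 8, median log2 ratio -2.24), chemokines (0 higher and 9 lower of 14, median -1.6, Il1b 10.1-fold) and G2 and M phase genes (0 higher and 11 lower of 14, median -1.21) were lower. Macrophage genes were also lower in Met-1 luminal-like cells, with C1qa at 10.4 CPM against 149 in PyMT and Lyz2 at 20.8 against 144, so the Cd74, antigen presentation and Il1b differences are not shown to be those of luminal cells. The immediate early list had a median of 0.65, or 0.39 without top cells (6 higher and 1 lower of 20), with Hspa1b 5.78-fold higher. The genes highest in Met-1 came from 1 cell of 107951 UMIs, which held 505 of 520 Met-1 UMIs of Col1a1, 494 of 499 of Col1a2, 446 of 460 of Sparc and 459 of 461 of Scgb1b27. The collagen list had a median of 2.11 with this cell and -1.0 without the top cell. Of 4626 genes, 271 were higher and 334 lower, but 191 and 80 with 50 UMIs in both libraries (65.0 and 28.6 CPM). The numbers were 78 and 184 of 3996 after the median over the other classes was taken away (175 and 225 before). Of these genes, 39 and 102 were in both counts.

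T-like cells (330 and 48) were higher in Met-1 for the granzyme Gzmc (16.9-fold, 10.1 to 31.0), Lars2 (18.8-fold, 6.40 to 91.3, 3 PyMT UMIs), Hnrnpa0 (10.2-fold, 6.18 to 18.3) and the chemokine Ccl1 (at least 14.9-fold, 242 of 458 UMIs in 1 cell). C1qa, C1qb, Il1b and Cd74 were 14.2-fold, 10.1-fold, 9.96-fold and 7.42-fold lower, but 64 of 79, 68 of 79, 53 of 72 and 470 of 523 of their PyMT UMIs were in 1 cell. Of 5589 genes, 492 were higher and 161 lower in T-like cells (75.3% of genes apart higher, 91.3% after the centring used for fibroblast-like cells). With 50 UMIs in both libraries (17.1 and 175 CPM), 10 were higher and 68 lower. After the median over the other classes was taken away, 105 of 5061 were higher and 133 lower (420 and 141 before). Of these genes, 72 and 33 were in both counts. B-like cells (260 and 31) were higher in Met-1 for Hspa1b (27.8-fold, 7.68 to 230, 2 PyMT UMIs), EGFP, Lncpint (at least 3.87-fold) and Zfp292 (at least 3.14-fold), and lower for Fcrl1 (3.99-fold), Zfp36l2 (3.66-fold) and Crem (3.56-fold). Of 2498 genes, 491 were higher and 111 lower in B-like cells (81.6% higher, 93.9% after that centring), but 8 and 24 with 50 UMIs in both (50.3 and 705 CPM). The numbers were 268 and 78 of 2359 after the other classes were taken away (463 and 108 before), with 235 and 21 genes in both counts. Several named genes were at least 2-fold apart in the same direction in each of the 3 to 5 other classes with a value, so they do not mark a class. These were Lars2, Hnrnpa0 and Gzmc of T-like cells, Lars2, Mgp and Vmn1r13 of macrophage-like cells, Jdp2 of neutrophil-like cells, Cxcl2 of luminal-like cells and Lncpint of B-like cells. The same held for Tagln, Rcan1, Cxcl1, Chil3 and Egln3 in the 1 or 2 other classes with a value.

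RNA of G2 and M phase genes was detected in more macrophage-like cells of the Met-1 transplant. Summed over this class, 3 of 24 G2 and M phase genes were higher and 21 under 2-fold (median log2 ratio 0.36). S phase genes of this class were not apart (0 of 21, median log2 ratio -0.04). At 1000 UMIs, 16.1% (13.6 to 18.9) of Met-1 and 7.14% (3.96 to 11.7) of PyMT macrophage-like cells held at least 2 UMIs of G2 and M phase genes (63.3% and 53.7% without thinning), with 36 and 7 cells left out for depth. Among T-like cells the shares were 16.9% (13 to 21.4) and 27.1% (15.3 to 41.9), or 70.0% and 54.2% without thinning, with 4 and 0 cells left out. Luminal-like cells were 0 of 31 in Met-1 (up to 11.2%) and 10.5% (5.16 to 18.5) in PyMT, or 43.9% and 57.6% without thinning, with 10 and 4 cells left out. Neutrophil-like cells, in which Hmgb2 was the only measured gene of these phases, stood at 24.2% and 18.0% (67.6% and 30.4% without thinning, 4 and 13 left out). Met-1 fibroblast-like cells stood at 1.36% (33.9% without thinning).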

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

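The tests in this part were chosen only after the result was seen. A cluster of the Met-1 transplant held 87 cells with markers of both macrophages and B cells, against 3 cells in the PyMT tumour, had the highest median doublet score of all clusters (0.0367) and entered no class comparison. Cd79a stood 67.76-fold (53.9 to 86.3) higher in these cells than in macrophage-like cells and was present in 87 of 87. The cluster was called mixed by its B cell markers, Cd79a among them, so these values do not decide on free B cell RNA. Random pairs of cells in a droplet were argued against, because macrophage and T cell markers met in 7 cells and macrophage and B cell markers in 102, a ratio per T-like and B-like cell of 0.05448 (0.0214 to 0.116). The profile lay close to a sum of both types weighted 26.7% to B-like RNA, with 99.84% of 3113 genes within 2-fold of it against 96.7% for macrophage-like RNA alone, and 100% against 3.41% of the 88 genes at least 4-fold higher in B-like than in macrophage-like cells. Whether such cells could be macrophages and B cells held together in the tumour or joined while cells were isolated stays open, and no biological explanation was tested.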

How the results depend on the processing

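Other settings were compared for 68 results, giving 456 values, of which 305 kept the direction and size (289 planned and 16 added), 148 moved (125 planned and 23 added) and 3 reversed (all added). By kind, 7 of 132 class share values moved, as did 81 of 164 gene counts, 9 of 84 list medians with 3 more reversed, 6 of 16 list member counts, 2 of 4 subcluster shares and 43 of 56 thinned shares. List medians were computed in all settings for 4 lists only, and these are the medians counted here. No paired analysis was possible because each group has 1 library with replicate number 1. The added alternatives were chosen after seeing the data and are the Clec3b cluster alone, each gene without its top cell, 50 UMIs in both libraries, and the share of fibroblast-like and mural-like cells combined. The values of that combined share are nonetheless counted above with the planned ones. Gene counts below are at least 2-fold higher, then lower, in Met-1.

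Class shares stayed close apart from the fibroblast-like share of Met-1, which was 3.93% with a mitochondrial limit of 20%, 4.06% at resolution 0.3, and 4.01% with 1000 variable genes or with 2 times the main number. In these settings the cluster led by Cilp and Thbs4 joined the mural-like cells, and the genes of fibroblast-like cells numbered 548 and 180 with the limit of 20%, and 538 and 177 in the other 3. The combined share of fibroblast-like, mural-like and joined cells was 17.4% in Met-1 and 17.1% to 19.0% over the settings. With all barcodes, the Met-1 macrophage-like share was 33.2%, the PyMT immune share 77.5% and the PyMT combined share 4.69%, and the cause was not tested.

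For fibroblast-like cells the number of genes apart depended on the setting. There were 585 lower with 1 CPM added, 274 and 172 with 50 CPM added, 608 and 163 with 200 summed UMIs, 11 and 94 with 50 UMIs in both libraries, and 644 lower without a minimum. Centring on the median of genes with 50 UMIs in both libraries gave 2699 and 151. Drawing Met-1 to 11 cells gave 85 and 112, and the inflammatory list then had a median of -2.01. Leaving out the top cell of each gene gave 3178 and 130, with medians of -0.17 for the adipose progenitor list and 1.12 for collagens. By construction this takes more from 11 cells than from 224. The myofibroblastic median was 2.43 with 1 CPM and 1.12 with 50 CPM added. In the Clec3b cluster alone there were 538 and 177 genes, and 3 of the 4 medians reversed, to -0.21 for the myofibroblastic, 0.15 for the inflammatory and 0.047 for the adipose progenitor list. Members of these lists mark the kept cluster or the one left out, so the reversals are in part built in. Outside these 4 lists, medians of the other sign were 0.18 for immediate early, 0.03 for TGF-beta, -0.04 for S phase and -0.07 for Wnt and Notch genes in the Clec3b cluster. Without top cells they were 0.07 for immediate early, 0.43 for TGF-beta, 0.45 for YAP and TAZ and 0.65 for hypoxia genes. With a 1.5-fold rule, 3 adipose progenitor genes were higher and 3 collagens lower.

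Over all kept cells, there were 2202 and 763 genes with 1 CPM added, 196 and 131 with 50 CPM, 260 lower with 200 summed UMIs, and 454 higher with 50 UMIs in both. The myofibroblastic median was 3.05 with 1 CPM, 1.12 with 50 CPM and 1.57 with the mean of each cell's CPM, and the collagen median was 1.75 with 50 CPM. With a 1.5-fold rule, inflammatory genes numbered 11 and 8 and adipose progenitor genes 12 and 4.

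In macrophage-like cells there were 1159 higher with 1 CPM, 77 and 42 with 50 CPM, 49 lower with 200 summed UMIs, 175 higher with 50 in both and 799 higher with the mean of each cell's CPM. T-like cells had 810 and 279 with 1 CPM, 52 and 57 with 50 CPM, 164 and 61 with 200 summed UMIs, 10 and 68 with 50 in both, 814 and 78 when centred, 358 lower without a minimum, 102 and 92 with equal numbers of cells, and 835 and 73 without top cells. B-like cells had 207 and 54 with 50 CPM, 66 and 28 with 200 summed UMIs, 8 and 24 with 50 in both, 44 lower when centred, 2003 and 1005 without a minimum, 32 and 26 with equal numbers of cells, and 771 and 51 without top cells.

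Luminal-like cells had 109 and 116 with 50 CPM, 55 and 140 with 200 summed UMIs, 191 and 80 with 50 in both, 589 lower with the mean of each cell's CPM, 611 higher without a minimum, 210 lower with equal numbers of cells, and 128 higher without top cells. Neutrophil-like cells had 10 and 54 with 200 summed UMIs, 34 and 18 with 50 in both, 1121 and 1170 without a minimum, 45 lower with equal numbers of cells, and 31 higher without top cells.

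Shares of cells with a UMI depend on depth by construction. At 2000 UMIs, adipocyte markers were seen in 9.26% of Met-1 fibroblast-like cells and in 16.4% and 15.5% of Met-1 and PyMT macrophage-like cells. Lpl was seen in 54.6% of Met-1 fibroblast-like cells and in 24.9% and 14.9% of macrophage-like cells. Cycling cells at that depth were 29.4% and 18.2% of macrophage-like, 28.6% of Met-1 T-like, 53.6% and 38.8% of neutrophil-like and 17.4% and 21.5% of luminal-like cells.

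Without thinning, markers were seen in 32.6% and 36.4% of fibroblast-like and 41.3% and 50.7% of macrophage-like cells, and Lpl in 85.3% and 81.8%, and 45.5% and 29.1%, of the same classes. Cycling cells were then 63.3% and 53.7% of macrophage-like, 70.0% and 54.2% of T-like, 67.6% and 30.4% of neutrophil-like and 43.9% and 57.6% of luminal-like cells. With doublet calls kept, markers were seen in 4.09% of Met-1 fibroblast-like cells, and the cause was not tested. With 3 UMIs for a cycling cell, the shares were 7.48% and 3.57% of macrophage-like, 9.82% of Met-1 T-like, and 9.09% and 3.93% of neutrophil-like cells. With 1 UMI, they were 39.1% and 24.5%, 43.3% and 54.2%, 54.5% and 41.6%, and 12.9% and 23.2% of macrophage-, T-, neutrophil- and luminal-like cells. At a subcluster resolution of 0.8, 5 subclusters were found and the 1 with the most Acta2 held 18.8% of Met-1 and 0% of PyMT fibroblast-like cells.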

Other observations

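The tests in this part, and the genes named in it, were chosen only after the result was seen. Within Met-1 fibroblast-like cells, EGFP and Lpl were highest in the subcluster led by Spp1 and Acta2 (EGFP 2849 CPM, 2788 to 2911; Lpl 993 CPM, 957 to 1030), and lower in that led by Gdf10 (1300 and 410 CPM) and that led by Pi16 and Dpp4 (1696 and 219 CPM). The chemokine Cxcl14 was highest in the Gdf10 subcluster (1138 CPM, 1046 to 1235; 8.25 CPM in the Pi16 subcluster), as was the fatty acid carrier Fabp4 (88.0 CPM, 63.9 to 118). RNA of adipocyte genes was most abundant in 1 Met-1 cell of the macrophage-like cluster led by Aif1, with 248 UMIs of Cfd, 68 of Fabp4, 62 of Lpl, all 5 of Adipoq, 48 of EGFP, 59 of Prg4 and 0 of C1qa. A second cell held 119 of Cfd, 20 of Car3, 18 of EGFP and 23 of Prg4, but 0 of Adipoq and Lpl and 1 of Fabp4. Another cell of this cluster held 7 of Plin4, 13 of Fabp4, 4 of Cfd, 163 of EGFP and 188 of Prg4, and 0 of Adipoq and C1qa. These cells entered the macrophage-like comparison, where the first and second hold 367 of 373 Met-1 Cfd UMIs.

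EGFP RNA was present in the immune classes of the Met-1 transplant, although the label is driven by an adipocyte promoter. Free EGFP RNA in droplets was argued against, because T-like cells, the immune class with the least EGFP, had 12.35-fold (10.6 to 14.5) more of it than luminal-like cells. Droplets shared with a labelled fibroblast-like or mural-like cell were argued against, because 95.17% (92.3 to 97.2) of the 331 B-, T- and NK-like cells without a UMI of a fibroblast or mural marker held EGFP, against 58.5% of luminal-like cells at a like depth (medians 5515 and 5302 UMIs). Whether the label could be active in blood cells or their precursors stays open, because Cre and rtTA are not in the gene table, and no biological explanation was tested.

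Of 658 genes measured in 6 classes, 23 were at least 2-fold apart in the same direction in at least 5 classes, 5 higher and 18 lower in Met-1. Chance acting on each class separately was argued against, because 1000 shuffles of the genes within classes gave at most 1 such gene. All classes come from the same 2 libraries, so the shuffles do not cover a chance difference between the libraries. In all 6 classes, Gm42418 was higher (median log2 ratio 5.94) and 15 genes were lower, most of them ribosomal, with Rpl13a at -2.78 and Ftl1 at -1.16. The barcode sets of the 2 libraries differed, as the first 6 bases of 29.4% (25.8 to 33.2) of PyMT barcodes also start a Met-1 barcode. Random draws within the Met-1 library gave a mean of 84.8% (range 81.26 to 88.85). These values meet a criterion for different library preparations that was written after the results were seen. The test could only argue against that cause or leave it open, and it left it open. How far preparation accounts for these genes, or for any other ratio between the libraries, stays open because preparation and tumour model cannot be separated here.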
